A study of Mus musculus with 13 samples.

How the data were processed

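Total RNA of 4T1 tumours was labelled as biotinylated cRNA and hybridised to Illumina bead arrays, per the labels' protocols. Samples were put in groups from their titles: 9 arrays in 3 groups of 3 on 1 platform (45281 probes), and 4 arrays, 1 per group, on another (25697 probes). The labels state the same positive transgene field for every sample, wild-type hosts included, so groups were taken from the titles.

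The deposited tables give, per the file headers, a probe signal (an intensity on a linear scale, not normalised and without background subtraction) and a detection p-value for each probe and array. The submitters' processing notes name GenomeStudio; its version, probe annotation and filters are not given in the sources used here. The authors' processed intensity values were found to be, on each array, a linear function of the deposited signal (largest residual 0.109), so that the authors took off 1 constant and applied 1 factor per array. They are on a linear scale, go below 0 and are not centred. Their medians were 12.6 to 19.4 on the 9 arrays and 21.5 to 28.1 on the 4. Of the columns of the larger table, 6 columns, for 3 arrays, match no sample here and were not used. In the smaller table the detection column of the late control array repeats its signal, so it was not used.

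For the 9 arrays, signals were background-corrected with the detection p-values and quantile-normalised (limma's neqc, offset 16). Probes with detection p below 0.05 on at least 3 of 9 arrays were kept, and each gene was represented by the probe with the highest mean log2 signal, which left 11057 genes. For the 4 arrays, for which neqc had been chosen, background was corrected with normexp (offset 50) and signals were quantile-normalised, because of the late control's column. Probes detected on at least 1 of 4 arrays were kept (9714 genes). On the late control array a probe counted as detected when its signal was within the top 42.6%, the smallest detected share of the other 3. Here normexp took off about as much as the offset adds, so leaving out the correction moved little. The platforms were normalised apart and only compared through differences within each.

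Probes were named from the platform annotation. Of 45281 probes 34885 had 1 gene symbol, 18 several and 10378 none; of 25697 probes 23978 had 1 and 1719 none. Symbols were checked through gene identifiers against RefSeq names of GRCm38.p6, with 34807 and 23962 probes matched. No genome build applies to these values and no coordinates are given. Where several probes of a named gene passed the filter, they were compared for direction.

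Groups were compared with limma (lmFit and eBayes) over all 9 arrays, so that the groups share 1 estimate of the spread, with Benjamini-Hochberg adjustment at 0.05. Gene lists for cell types and pathways (26 lists) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, where at least 5 members passed the filter. limma's fry was run beside it; its p depends on the order of the groups in the design, so all 6 orders were run, chosen after seeing the data, and a list was named only where it passed in each. For TK/IgG minus WT/IgG the count at an unadjusted p below 0.05 was 1 or 2 by order. The milk list had 4 and was tested only in the pairs; lymphatic and nerve lists were tested only on the 9 arrays. List members not on the annotated probes were not analysed here. In the pairs, list medians were placed among 10000 random lists of the same size matched on mean signal in 20 bins. A probe not above background on any array of a group was given as a bound, the mean of the bright group against the lowest signal of detected probes or the probe's own if higher. Single genes and list means were also compared by two-sided exact permutation, which with 3 against 3 cannot go below 0.1. The shared arrays of the first 2 comparisons were treated by 1000 simulations of unchanged groups.

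Genes were named by a fixed rule. It takes 9 genes always (Pdgfrb, Angpt2, Angpt1, Tek, Cspg4, Rgs5, Pecam1, Cdh5, Vegfa). With fewer than 5 genes past the threshold in a direction it takes the 5 with the smallest p. It takes up to 4 members of each list that passed, those with the largest differences, and in each pair the 10 largest ratios each way among genes brighter than the median. Other genes that passed adjusted over the list alone were named after their values were seen. The design, lists, naming rule and most alternatives were fixed before the data were examined. Alternatives varied the background correction, normalisation, value source, detection filter, probes per gene, samples in the fit, array weights, variance moderation, replicate block and each array left out. For these, a gene within 1 standard error of 0 was taken to have no direction. For the pairs, spread was borrowed from the median residual SD of the 9 arrays, and a gene counted as turned only if its ratio was at least 1 in size.

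The fit was tested on simulated arrays with 200 genes changed, for TK/IgG minus WT/IgG over 11057 genes. It recovered 44.8% of changes of 1 on the log2 scale, 92.5% of changes of 2 and 100% of changes of 3, with 6 false calls. The simulated noise was normal and independent between genes and arrays, at each gene's estimated SD. The real arrays are not independent in this way, so these shares need not hold for them. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.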

Results

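RNA from 4T1 mammary tumours was measured on Illumina bead arrays. 4T1 is a mouse mammary carcinoma line, grown here in the mammary fat pad of mice. In PDGFRb-TK mice a viral thymidine kinase is made by cells that use the Pdgfrb promoter, chiefly pericytes, and ganciclovir (GCV) then kills those of them that divide. The labels give GCV injection for every sample. On 1 platform, 9 arrays formed 3 groups of 3: wild-type hosts given control IgG (WT/IgG), PDGFRb-TK hosts given control IgG (TK/IgG) and PDGFRb-TK hosts given an antibody to angiopoietin-2 (TK/anti-Ang2). On another platform, 4 arrays formed an early and a late pair, each of 1 tumour with pericyte ablation and 1 control. The share of probes detected on the 9 arrays was 40.6 to 43.2%, and the median probe signal was 119.1 to 134.7. The number of arrays limits the precision. Nothing in the labels states that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

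Of the 9 arrays, TK/anti-Ang2 replicate 2 stood apart. Its median correlation with the other 8 across genes was 0.931, against 0.968 to 0.977 for the others. Its mean log2 signal lay above the next highest array by 1.34 for the adipocyte list, 2.54 for the skin keratinocyte and hair list and 2.24 for the mast cell list.

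The first comparison asked how targeting of Pdgfrb-expressing cells altered the tumours under control antibody. Pdgfrb, the platelet-derived growth factor receptor of pericytes and fibroblasts, had a log2 signal of 5.99 ± 0.31 (SD, n = 3) in TK/IgG tumours and 7.09 ± 0.21 (n = 3) in WT/IgG tumours. As a group, fibroblast and interstitial matrix genes were lower in TK/IgG tumours, with a median log2 difference of -0.54 and 29 of 32 members lower (adjusted p = 0.521 with an estimated correlation). Genes of the p53 response and cell death were higher, with a median of 0.24 and 15 of 17 members higher (adjusted p = 0.426 with an estimated correlation). Pericyte and mural cell genes had a median of -0.17, with 14 of 18 members lower, which did not pass the list test (adjusted p = 0.0930, and 0.521 with an estimated correlation). They passed at the preset correlation without TK/IgG replicate 3 (-0.31), which was not repeated with an estimated one.

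In limma's test of 11057 genes, 0 passed an adjusted p of 0.05, and 325 had an unadjusted p below 0.05 (137 higher and 188 lower in TK/IgG), where 553 were expected by chance. Without WT/IgG replicate 2 the latter count was 205. The 3 arrays of each group did not overlap for 8.27% of genes, where chance gives 10%. The Pdgfrb difference was -1.10 (SE 0.26), with a limma adjusted p of 0.999 over all genes. Adjusted over the list alone it was 0.0358. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. The gene with the smallest p was Slc24a3, a sodium/calcium-potassium exchanger, at 7.39 ± 0.24 against 6.17 ± 0.19 (difference 1.22, SE 0.17, limma adjusted p = 0.495). Gpnmb, a transmembrane glycoprotein abundant in lipid-laden macrophages, differed by 1.47 (SE 0.24, limma adjusted p = 0.999). Ripply3, Tbx2 and Slc23a3 followed on the higher side, with differences of 0.67, 0.56 and 0.73. On the lower side were Lin7a (-1.71), Brinp3 (-0.75), Sh3bp1 (-0.73), the homeobox gene Msx1 (-1.01) and H2ac21 (-0.73). Tbx2 was not above background on any WT/IgG array and Brinp3 on no TK/IgG array, which bounds them at no less than 1.07-fold and 1.24-fold.

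**Figure D1:**
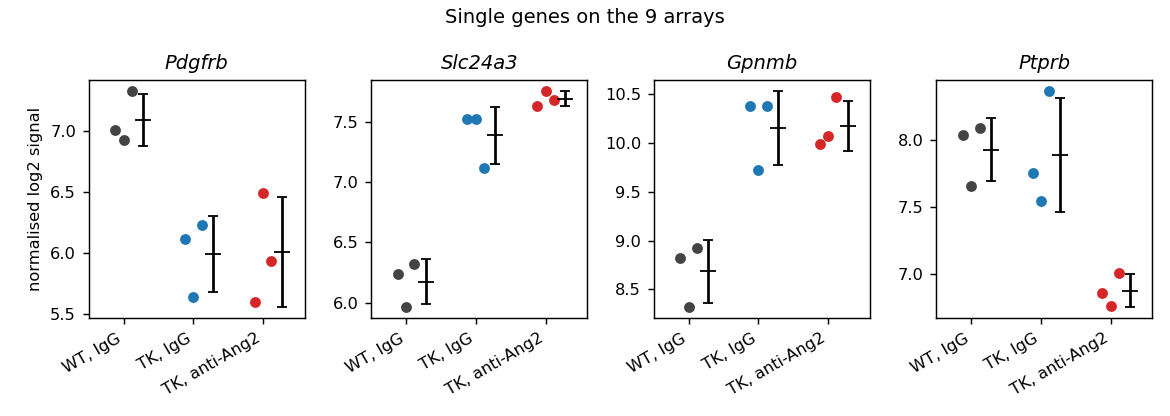
Normalised log2 signal of Pdgfrb, Slc24a3, Gpnmb and Ptprb on the 9 arrays, with each array as a point and the group mean and SD as a bar beside it (n = 3 per group). Pdgfrb averaged 7.09 in WT/IgG, 5.99 in TK/IgG and 6.005 in TK/anti-Ang2 tumours, and Ptprb averaged 7.93, 7.89 and 6.87.

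Among the genes fixed in advance, Angpt2, the angiopoietin to which the antibody binds, was at 10.56 ± 0.48 against 10.07 ± 0.15 (difference 0.49, SE 0.24), with a difference of 0.22 without TK/IgG replicate 1. Its receptor gene Tek differed by 0.02 (SE 0.26), Angpt1 by -0.08 (SE 0.29), the pericyte proteoglycan gene Cspg4 by 0.36 (SE 0.24) and the growth factor gene Vegfa by 0.31 (SE 0.33). Endothelial Pecam1 and Cdh5 differed by 0.34 (SE 0.32) and 0.03 (SE 0.31). A further detected probe of each gave the opposite sign, and Pecam1 turned to -0.07 without WT/IgG replicate 2. Vegfa turned to -0.06 without TK/IgG replicate 1, and Cspg4 was at 0.19 without WT/IgG replicate 1. Signs also turned for Angpt1 (0.04) without TK/IgG replicate 1, Tek (-0.15) without WT/IgG replicate 2 and Cdh5 (-0.25) without TK/IgG replicate 3. The limma adjusted p was 0.999 for each of these genes. Rgs5, a pericyte marker, was detected on 2 of 9 arrays and was not tested.

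Of 25 lists tested with limma's camera at a preset correlation, 11 passed, 9 higher and 2 lower in TK/IgG. The fibroblast list passed with an adjusted p of 5.72e-07. Its fall was led by the fibrillar collagen genes Col3a1 (-1.47) and Col1a1 (-1.14), the microfibril gene Mfap2 (-1.26) and the matrix proteoglycan gene Lum (-1.15). The call was lost with an estimated correlation (adjusted p = 0.521 with an estimated correlation). The p53 list passed with an adjusted p of 0.000165 (adjusted p = 0.426 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 0.95, the death receptor Fas at 0.67, Trp53inp1 at 0.59 and Phlda3 at 0.38. Fas and Phlda3 were at 0.43 and 0.19 without TK/IgG replicate 3, and Trp53inp1 at 0.38 without WT/IgG replicate 2. Both calls held when any array was left out, with a fibroblast median of -0.35 without WT/IgG replicate 1 and p53 medians of 0.38 and 0.12 without TK/IgG replicate 2 and WT/IgG replicate 2. None of the 11 calls held with an estimated correlation. With limma's fry, which asks only whether members move 1 way, the p53 list had an unadjusted p below 0.05, and the lowest adjusted p of any list was 0.466. For members adjusted over the list alone, 2 genes passed in all lists together, Pdgfrb and Gpnmb (0.00529), and 0 did over all genes.

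The other 9 calls each ended when at least 1 array was left out. Mesenchymal transition genes were lower (median -0.24, adjusted p = 0.00447), among them Twist2 (-1.96), Tnc (-0.80), Wnt5a (-0.77) and Mmp3 (-0.66). Tnc and Wnt5a were at -0.44 and -0.35 without TK/IgG replicate 2, and Mmp3 at -0.44 without WT/IgG replicate 2, while the 3 were at -1.36, -1.29 and -1.08 without TK/IgG replicate 1. That call ended without TK/IgG replicate 3 (-0.26) or WT/IgG replicate 1 (-0.20), with adjusted p = 0.436 with an estimated correlation. The T and NK cell list had a median of 0.20 (adjusted p = 0.00846; adjusted p = 0.696 with an estimated correlation) and the interferon list 0.16 (adjusted p = 0.0126; adjusted p = 0.777 with an estimated correlation). Without TK/IgG replicate 3 their medians were -0.21 and -0.10, and without WT/IgG replicate 1 they were -0.00495 and 0.00457. Their leading members were Prf1 (1.02), Ctla4 (0.81), Oas2 (0.91) and Isg15 (0.85), of which Oas2 and Isg15 were at 0.07 and 0.30 without TK/IgG replicate 3 and Prf1 at 0.27 without TK/IgG replicate 1. Oas2 was at 1.53 without TK/IgG replicate 1 and Ctla4 at 1.25 without TK/IgG replicate 2. Neutrophil and granulocyte genes had a median of 0.29 (adjusted p = 0.00447; adjusted p = 0.732 with an estimated correlation), with Hp at 1.10 (0.39 without WT/IgG replicate 2) and Cxcl2 at 0.90 (0.29 and 1.59 without TK/IgG replicates 1 and 2). That call ended without TK/IgG replicate 1 (0.09), TK/IgG replicate 3 (0.10) or WT/IgG replicate 2 (0.32). Some medians were higher with an array left out. Without TK/IgG replicate 2 those of the neutrophil, T and NK cell and interferon lists were 0.77, 0.50 and 0.39. The T and NK cell median was 0.35 without TK/IgG replicate 1 and 0.34 without WT/IgG replicate 3, and the interferon median 0.30 and 0.39 without TK/IgG replicate 1 and WT/IgG replicate 2.

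Chemokine and cytokine genes had a median of 0.20 (adjusted p = 0.00447; adjusted p = 0.732 with an estimated correlation), with Ccl3 at 1.38, Csf2 at 1.18 and Ccl4 at 1.05. Without TK/IgG replicate 1, Ccl3 and Ccl4 were at 0.66 and 0.67. The call ended without TK/IgG replicate 3 (0.19), WT/IgG replicate 2 (0.13) or WT/IgG replicate 3 (0.16). Angiogenic ligands and tip-cell genes had a median of 0.13 (adjusted p = 0.0427; adjusted p = 0.480 with an estimated correlation), with the tip-cell gene Esm1 at 1.41 (0.83 without WT/IgG replicate 2) and the lymphangiogenic factor Vegfc at 0.77. It ended without TK/IgG replicate 1 (0.01), TK/IgG replicate 3 (0.08), WT/IgG replicate 2 (-0.02), or TK/anti-Ang2 replicates 2 or 3 (0.13 each). Unfolded protein and stress response genes had a median of 0.16 (adjusted p = 0.00447; adjusted p = 0.480 with an estimated correlation), led by Ddit3 at 0.76 (0.41 without TK/IgG replicate 1), and ended without TK/IgG replicate 1 (0.07) or WT/IgG replicate 3 (0.12). Erythroid and platelet genes had a median of 0.79 (adjusted p = 0.00846; adjusted p = 0.585 with an estimated correlation), with haemoglobin genes Hba-a1 at 1.06 and Hbb-bt at 0.92 (0.44 and 0.26 without WT/IgG replicate 1, and 1.66 and 1.44 without TK/IgG replicate 2). They ended without TK/IgG replicate 1 (0.35), TK/IgG replicate 3 (0.52), WT/IgG replicate 1 (0.20) or the detection filter (0.11). Adipocyte genes had a median of 0.35 (adjusted p = 0.0180; adjusted p = 0.742 with an estimated correlation), and of -0.13 without TK/IgG replicate 2. Car3, at 1.28, was then at 0.18, and at 2.27 without TK/IgG replicate 1. The adipocyte call also ended without TK/IgG replicate 3 (0.48), WT/IgG replicate 1 (0.45) or replicate 2 (0.17), with the authors' processed values (0.28) and without the detection filter (0.09). Without the filter the T and NK cell call ended too (0.11). Higher medians came without TK/IgG replicate 2 for chemokine (0.43), angiogenic (0.23) and erythroid (1.34) genes, and without TK/IgG replicate 1 for adipocyte genes (0.77). Without WT/IgG replicate 1 the chemokine median was 0.51 and the angiogenic median 0.23, which was 0.22 without WT/IgG replicate 3.

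The 14 lists that did not pass had medians from -0.44 (skeletal muscle) to 0.33 (mast cell). Endothelial genes were at 0.00, macrophage genes at 0.05, hypoxia response genes at 0.07, cell cycle genes at -0.04 and epithelial genes at 0.15. Basement membrane genes were at -0.15, dendritic cell and MHC class II genes at -0.37, B and plasma cell genes at -0.10 and skin genes at 0.18. Lymphatic endothelial genes were at 0.20 and nerve and Schwann cell genes at 0.22. The endothelial mean was 0.04 and its test pointed up, while its median was just below 0. Some of these lists passed with 1 array left out, which was not repeated with an estimated correlation. Without TK/IgG replicate 1, endothelial, epithelial and macrophage genes passed as higher (0.20, 0.28 and 0.18), as did cell cycle genes without TK/IgG replicate 2 (0.18). MHC class II genes passed as lower without TK/IgG replicate 3 (-0.68) and cell cycle genes without TK/IgG replicate 1 (-0.20).

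The second comparison asked what the antibody to angiopoietin-2 added in targeted hosts. Endothelial cell genes were lower as a group in TK/anti-Ang2 than in TK/IgG tumours, with a median of -0.49 and 25 of 29 members lower (adjusted p = 0.622 with an estimated correlation). The mean log2 signal of the list was 7.31 ± 0.10 (SD, n = 3) against 7.77 ± 0.24 (n = 3), and the 3 arrays of each group did not overlap. Chemokine and cytokine genes were higher, with a median of 0.51 and 25 of 26 members higher, and hypoxia response genes were higher, with a median of 0.23 and 30 of 38 members higher (for each, adjusted p = 0.622 with an estimated correlation). TK/anti-Ang2 replicate 2 was the highest array in both lists, and without it their medians were 0.22 and 0.15. In both lists the arrays of TK/anti-Ang2 and TK/IgG overlapped, with an exact permutation p of 0.3 for each.

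limma called 0 genes, with 369 at an unadjusted p below 0.05 (141 higher and 228 lower), where 553 were expected by chance. Without TK/anti-Ang2 replicate 3 the latter count was 1077. Non-overlapping arrays were seen for 6.95% of genes, where chance gives 10%. The lowest limma adjusted p was 0.992. The smallest p values on the lower side were those of Rhbdf2 (-1.02), the semaphorin gene Sema7a (-1.29), Plekha3 (-0.74), Slc23a3 (-0.79) and Ptprb (-1.02, SE 0.23), the endothelial phosphatase that acts on the angiopoietin receptor. On the higher side were Dtl (0.56), the complement protease gene C1s1 (0.94), Chchd10 (1.13), Art3 (0.89) and Pltp (1.27). Dtl was not above background on any TK/IgG array, which bounds it at no less than 1.20-fold. Angpt2 differed by -0.15 (SE 0.24), Angpt1 by -0.31 (SE 0.29), Tek by -0.31 (SE 0.26), Cspg4 by -0.12 (SE 0.24), Vegfa by 0.16 (SE 0.33) and Pecam1 by -0.58 (SE 0.32). The second detected probe of Angpt2 went the other way. Without TK/IgG replicate 1 Angpt2 turned to 0.13. Angpt1 was at -0.02 and -0.54 without TK/anti-Ang2 replicates 2 and 3, and Tek at -0.53 without TK/anti-Ang2 replicate 2 and -0.16 without TK/IgG replicate 3. Vegfa turned to -0.11 without TK/IgG replicate 2 and Cspg4 to 0.07 without TK/anti-Ang2 replicate 3. Pdgfrb did not differ beyond its error, at 6.005 ± 0.45 against 5.99 ± 0.31 (difference 0.01, SE 0.26), and was at -0.23 without TK/anti-Ang2 replicate 2.

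Camera at the preset correlation passed 6 of 25 lists, 5 higher and 1 lower. The endothelial fall had an adjusted p of 5.00e-09 (adjusted p = 0.622 with an estimated correlation). Its leading members were the transcription factor gene Sox17 (-1.20), Ptprb, the junctional cadherin gene Cdh5 (-0.95, SE 0.31) and the tight junction gene Cldn5 (-0.91). Ptprb passed adjusted over the list alone (0.0443), the only such gene in this comparison, and 0 members passed over all genes. The chemokine list had an adjusted p of 6.48e-07 (adjusted p = 0.622 with an estimated correlation), with the B cell attractant Cxcl13 at 3.05, Ccl8 at 1.34, the acute-phase gene Saa3 at 1.32 and Ccl11 at 1.23. The last 3 were at 0.37, 0.73 and 0.77 without TK/anti-Ang2 replicate 2. The hypoxia list had an adjusted p of 7.54e-06 (adjusted p = 0.622 with an estimated correlation), with the collagen cross-linking gene Lox at 1.30, Angptl4 at 1.02, Adm at 0.98 and Rora at 0.96. Without the same array these 4 were at 0.75, 0.49, 0.54 and 0.22. Angptl4 was at 1.61 without TK/anti-Ang2 replicate 3 and Adm at 1.66 without TK/IgG replicate 1. None of the 6 calls held with an estimated correlation. By limma's fry, only the endothelial list had an unadjusted p below 0.05, and the lowest adjusted p was 0.828. These 3 calls held when any array was left out, and the endothelial median ranged from -0.66 to -0.38. TK/anti-Ang2 replicate 2 lay 0.57 above the next array in the chemokine list mean. The chemokine median was 0.22 without it and 0.81 without TK/anti-Ang2 replicate 3. Hypoxia medians were 0.15 and 0.35 without TK/anti-Ang2 replicates 2 and 3, and 0.37 and 0.12 without TK/IgG replicates 1 and 3.

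The remaining 3 calls ended without TK/anti-Ang2 replicate 2. The fibroblast list had a median of 0.48, with 30 of 32 members higher (adjusted p = 7.54e-06; adjusted p = 0.622 with an estimated correlation), and -0.02 without that array (0.78 without TK/anti-Ang2 replicate 3). Its leading members were Dpt (1.31), Pi16 (1.30), Lum (1.21) and Serping1 (0.94), at 0.30, 0.13, 0.15 and 0.15 without it (Lum and Serping1 at 1.91 and 1.47 without TK/anti-Ang2 replicate 3). Adipocyte genes had a median of 1.08 (adjusted p = 7.54e-05; adjusted p = 0.622 with an estimated correlation) and 0.33 without it (0.70 without TK/IgG replicate 1 and 1.72 without TK/anti-Ang2 replicate 3), led by Scd1 (2.14), Plin4 (2.08), Car3 (1.97) and Adipoq (1.83). Without TK/IgG replicate 1, Plin4 and Adipoq were at 1.11 and 0.70, and Car3 was at 0.84 without TK/anti-Ang2 replicate 2. Higher values were 2.96 for Adipoq without TK/IgG replicate 2 and 3.17 for Car3 without TK/anti-Ang2 replicate 3. Mast cell genes had a median of 1.24 (adjusted p = 0.00407; adjusted p = 0.622 with an estimated correlation) and 0.24 without TK/anti-Ang2 replicate 2, led by the protease genes Mcpt4 (2.08) and Cma1 (1.74), themselves at 0.83 and 0.57 without it. The mast cell call also ended without TK/IgG replicate 1 (0.95) and without the detection filter (0.72).

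The 19 lists that did not pass included pericyte and mural cell genes (median 0.06), macrophage genes (-0.03), cell cycle genes (0.14), neutrophil genes (0.16), interferon genes (0.11), T and NK cell genes (0.11) and skin genes (0.998, but -0.58 without TK/anti-Ang2 replicate 2). The macrophage list had an adjusted p of 0.897 with an estimated correlation. At the preset correlation it passed as lower without TK/anti-Ang2 replicate 2 (-0.22, adjusted p = 0.00112) or TK/IgG replicate 1 (-0.28, adjusted p = 0.0376), not repeated with an estimated correlation. Interferon, cell cycle and T and NK cell genes likewise passed as higher without TK/IgG replicate 3 (0.50, 0.24 and 0.40), neutrophil genes without TK/anti-Ang2 replicate 3 (0.66) and pericyte genes without TK/IgG replicate 3 (0.22). Medians for erythroid, basement membrane and angiogenic genes were -0.59, -0.12 and -0.11. The p53 list had a median of -0.04, a mean of 0.06 and a test that pointed up, and the macrophage list had a mean of 0.01 and a test that pointed down.

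**Figure D2:**
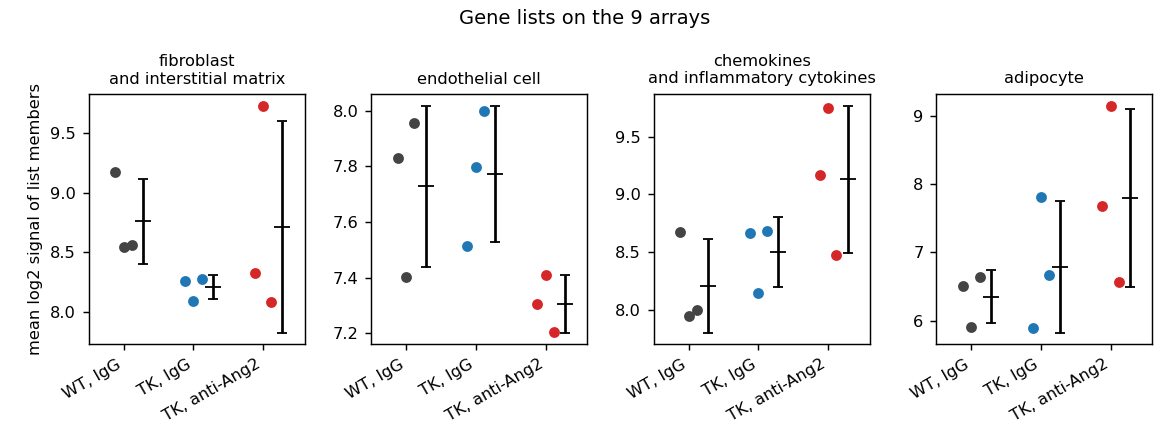
Mean log2 signal of the members of 4 gene lists on the 9 arrays, with each array as a point and the group mean and SD as a bar beside it (n = 3 per group). Endothelial means were 7.73, 7.77 and 7.31 in WT/IgG, TK/IgG and TK/anti-Ang2 tumours, and TK/anti-Ang2 replicate 2 is the highest point for the fibroblast (9.73), chemokine (9.75) and adipocyte (9.15) lists.

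The third comparison set targeting together with the antibody against wild-type hosts. Chemokine and cytokine genes were higher in TK/anti-Ang2 than in WT/IgG tumours, with a median of 0.91 and 24 of 26 members higher (adjusted p = 0.345 with an estimated correlation; median 0.52 without TK/anti-Ang2 replicate 2). Endothelial genes were lower, with a median of -0.45 and 27 of 29 members lower (adjusted p = 0.416 with an estimated correlation). Genes of the p53 response, the unfolded protein response and the hypoxia response were higher, with medians of 0.20, 0.29 and 0.27 (adjusted p = 0.313, 0.313 and 0.487 with an estimated correlation). Arrays of TK/anti-Ang2 and WT/IgG overlapped in the chemokine, endothelial and hypoxia list means, with an exact permutation p of 0.2 for each. They did not overlap in the p53 and unfolded protein list means (exact permutation p = 0.1 for each). Pdgfrb was at 6.005 ± 0.45 (SD, n = 3) against 7.09 ± 0.21 (n = 3), a difference of -1.09 (SE 0.26).

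limma called 0 genes, with 817 at an unadjusted p below 0.05 (320 higher and 497 lower), where 553 were expected by chance. The latter count was 491 and 1519 without TK/anti-Ang2 replicates 1 and 3, and 515 and 461 without WT/IgG replicates 2 and 3. Non-overlapping arrays were seen for 12.6% of genes, where chance gives 10%. Slc24a3 had the lowest limma adjusted p, 0.0823 (7.70 ± 0.06 against 6.17 ± 0.19, difference 1.52, SE 0.17). It passed in 3 other settings (limma adjusted p 0.0278 to 0.0431). Over all alternative settings its limma adjusted p ran from 0.0278 to 0.573. Next on the higher side were Denn2b (0.86), Gpnmb (1.49), the osteoprotegerin gene Tnfrsf11b (1.47) and Fas (1.48). On the lower side were Col15a1, a collagen of vascular basement membrane zones (-1.07, SE 0.17), Stard9 (-0.76), the Notch target Nrarp (-0.79), Coa7 (-0.71) and Msx1 (-1.02). The limma adjusted p of Pdgfrb was 0.672 over all genes and 0.0383 adjusted over the list alone, with an exact permutation p of 0.1, the smallest possible. Angpt2 differed by 0.35 (SE 0.24), Angpt1 by -0.40 (SE 0.29), Tek by -0.29 (SE 0.26), Cspg4 by 0.24 (SE 0.24), Pecam1 by -0.24 (SE 0.32) and Vegfa by 0.47 (SE 0.33). Angpt1 and Cspg4 were at -0.11 and 0.07 without TK/anti-Ang2 replicate 2, Tek at -0.51 and -0.14 without TK/anti-Ang2 replicates 2 and 3, and Pecam1 at -0.65 and -0.02 without WT/IgG replicates 2 and 3. Without TK/anti-Ang2 replicate 3, Angpt1 and Cspg4 were at -0.63 and 0.42.

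Camera passed 13 of 25 lists, 11 higher and 2 lower, none of them with an estimated correlation. In limma's fry 4 lists had an unadjusted p below 0.05 (endothelial, basement membrane, unfolded protein and p53), with a lowest adjusted p of 0.257. Adjusted over the list alone, 15 list members passed, against 0 over all genes. Of these, 5 were in the chemokine and cytokine list: Cxcl13 (2.97), the neutrophil attractant Cxcl1 (1.95), Ccl4 (1.41), the growth factor gene Csf2 (1.19) and Tnfaip3 (0.90). The others were Pdgfrb, Ptprb (-1.05), Cxcl12 (1.65), C1s1 (0.87), Col15a1, Gpnmb, the interleukin-7 receptor gene Il7r (0.83), Cdkn1a (1.48), Fas and the carbonic anhydrase gene Car2, which was at least 1.74-fold higher since it was not above background in WT/IgG. The chemokine list had an adjusted p of 1.08e-10 (adjusted p = 0.345 with an estimated correlation), and also held Ccl3 (1.72) and Ccl8 (1.71). Its median was 0.52 without TK/anti-Ang2 replicate 2, and Ccl8 was then at 0.74. The endothelial list had an adjusted p of 1.04e-05 (adjusted p = 0.416 with an estimated correlation), with Sox17 at -1.16, Cldn5 at -0.92 (-1.42 and -0.48 without WT/IgG replicates 2 and 3) and Cdh5 at -0.92 (SE 0.31).

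The p53 list had an adjusted p of 0.000394 (adjusted p = 0.313 with an estimated correlation), with Gadd45b at 1.10 beside Cdkn1a and Fas. Its median was 0.30 without TK/anti-Ang2 replicate 1 and 0.0912 and 0.33 without WT/IgG replicates 2 and 3. The unfolded protein list had 0.000139 (adjusted p = 0.313 with an estimated correlation), led by Ddit3 at 1.11. The hypoxia list had 2.09e-05 (adjusted p = 0.487 with an estimated correlation), led by Adm (1.17), Angptl4 (1.10) and Lox (1.05), at 0.73, 0.57 and 0.51 without TK/anti-Ang2 replicate 2 (Angptl4 at 1.70 without replicate 3). Adipocyte genes had a median of 1.44 (adjusted p = 2.52e-07; adjusted p = 0.439 with an estimated correlation), led by Car3 (3.25) and Adipoq (2.61), and a median of 0.70 without TK/anti-Ang2 replicate 2, where these were at 2.13 and 1.63.

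The other calls ended when some arrays were left out. Basement membrane genes (median -0.28, 13 of 15 members lower, adjusted p = 0.0209; adjusted p = 0.313 with an estimated correlation), with Lama5 at -0.66 (-0.38 without TK/anti-Ang2 replicate 2), Lamb1 at -0.59 and Hspg2 at -0.54, had medians of -0.22, -0.37 and -0.09 without TK/anti-Ang2 replicate 1, TK/anti-Ang2 replicate 3 or WT/IgG replicate 3. Epithelial genes (median 0.20, adjusted p = 0.00714; adjusted p = 0.487 with an estimated correlation) included the keratin gene Krt14 (1.79, and 0.99 without TK/anti-Ang2 replicate 2). They had medians of 0.12 without TK/IgG replicate 3, 0.10 and 0.25 without TK/anti-Ang2 replicates 1 and 3, and 0.06 without WT/IgG replicate 1, while without WT/IgG replicate 3 the median was 0.34. Neutrophil genes (median 0.47, adjusted p = 0.00328; adjusted p = 0.584 with an estimated correlation), led by Hp (2.68), had 0.28 and 0.20 without TK/anti-Ang2 replicates 1 and 2, and 1.001 without replicate 3. T and NK cell genes (median 0.24, adjusted p = 0.00382; adjusted p = 0.487 with an estimated correlation), led by Cd3g (1.15, and 0.58 without WT/IgG replicate 1), had 0.21 without WT/IgG replicate 1, where the call ended. Their median was 0.57 without WT/IgG replicate 3, 0.37 without TK/IgG replicate 1 and 0.38 without TK/anti-Ang2 replicate 2. Interferon genes (median 0.25, adjusted p = 0.00349; adjusted p = 0.685 with an estimated correlation), led by Oas2 (1.12), had 0.15 and 0.03 without TK/anti-Ang2 replicates 1 and 3 and 0.02 without WT/IgG replicate 1, but 0.58 without TK/anti-Ang2 replicate 2 and 0.40 without WT/IgG replicate 2. The skin list (median 1.30, adjusted p = 0.00708; adjusted p = 0.487 with an estimated correlation) had -0.27 without TK/anti-Ang2 replicate 2, and 2.22, 2.38 and 2.001 without TK/anti-Ang2 replicates 1 and 3 and WT/IgG replicate 3. The mast cell list (median 1.80, adjusted p = 0.000394; adjusted p = 0.477 with an estimated correlation) had 0.84 without TK/anti-Ang2 replicate 2, where its call ended, and 1.03 without WT/IgG replicate 2. Among skin genes, Trp63 was at 1.89, Krt15 at 1.75, Lce1c at 1.66 and Krt10 at 1.54. Without TK/anti-Ang2 replicate 2, Trp63 was at 0.82 and the other 3 turned to -0.15, -0.40 and -0.14. Higher values were 2.90 for Krt15 without replicate 1 and 2.90 and 2.53 for Lce1c and Krt10 without replicate 3 of that group. In mast cell genes, Mcpt4 was at 2.14 and Cpa3 at 2.08, and at 0.89 and 0.91 without TK/anti-Ang2 replicate 2.

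Of the 12 lists that did not pass, the fibroblast list had a median of -0.08 (-0.69 without TK/anti-Ang2 replicate 2, where it passed as lower at the preset correlation, not repeated with an estimated one), the pericyte list -0.07, the angiogenic list 0.23 and the mesenchymal list -0.15. Erythroid genes had a median of -0.62 and a mean of -0.14 but a test that pointed up. Macrophage, B cell and skeletal muscle medians were -0.10, -0.03 and -0.04, also with tests that pointed up. The macrophage and B cell means were 0.06 and 0.07.

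Across 11057 genes, which are not independent replicates, the effect of targeting (TK/IgG minus WT/IgG) and that of the antibody (TK/anti-Ang2 minus TK/IgG) had a correlation of -0.18. Both use the TK/IgG arrays, and simulated groups with no effect gave a mean of -0.46, with 95% of values from -0.95 to 0.50. The covariance was -0.0146, against a simulated mean of -0.0575 (-0.205 to 0.0362), a difference of 0.0429. With each array left out in turn it ranged from -0.0544 (without TK/IgG replicate 3) to -0.00549 (without WT/IgG replicate 1), and the simulation was not repeated for these. With 3 shared arrays, a split that keeps enough libraries on each side could not be made. Both values lay inside the simulated range, so neither was told apart from what the shared arrays alone give.

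The early and late pairs asked what ablation did at an early and at a late stage of tumour growth. With 1 array per group they have no replicate check, and all values describe these libraries. Of 24 lists, 13 in the early and 14 in the late pair lay outside the central 95% of random lists. Genes of a random list were drawn independently, which does not allow for correlated members. A place outside the random lists is thus no test of an effect of ablation. The labels give the 2 controls the PDGFRb-TK genotype in 1 field and wild type in another, so they are named control libraries. In the early pair, skeletal muscle genes were far higher in the ablated tumour, and neutrophil genes were higher. In the late pair, fibroblast and interstitial matrix genes, endothelial genes and pericyte genes were lower in the ablated tumour, and neutrophil, interferon and chemokine genes were higher. Pdgfrb was at 7.04 in the ablated and 6.98 in the control tumour early, and at 6.68 and 7.46 late (log2 ratio -0.78). The early pericyte list (-0.05) lay inside the random lists, so in these libraries its genes did not show the ablation named in the early label. Des, on this list and also a muscle gene, was at 3.23 in the early pair, the 1 member higher by at least 1. Whether muscle RNA in the ablated tumour hid a fall of other members was not tested.

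In the early pair, 106 of 9714 genes had a log2 ratio of at least 1 in size, 92 higher and 14 lower in the ablated tumour. With the authors' processed values there were 201. The skeletal muscle list had a median of 2.21, with 22 of 28 members higher by at least 1. The contractile and calcium-pump genes Acta1, Myl1, Atp2a1 and Tnnc2 were at least 63.0-fold, 38.3-fold, 34.1-fold and 20.8-fold higher, since they were not above background in the control. The muscle genes Csrp3 and Mylpf were at least 8.62-fold and 8.64-fold higher, and Des and Fhl1 had log2 ratios of 3.23 and 2.76. Neutrophil genes had a median of 0.43, above all of 10000 random lists matched on signal, with S100a8 at 2.52, Retnlg at 2.13 and S100a9 at 1.85. B and plasma cell genes (0.43, with Fcmr at least 2.98-fold higher), mast cell genes (0.48, with Tpsab1 at 0.82) and chemokine genes (0.27, with Cxcl1 at 1.69 and Saa3 at 1.52) also lay above all random lists. Macrophage genes (-0.36, with Apoe at -1.01 and C1qb at -1.005) and dendritic cell and MHC class II genes (-0.33, with H2-Eb1 at -1.07) lay below all of them.

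Angiogenic (0.22, with Adm at 0.98 and Vegfa at 0.71), hypoxia (0.14, with Lox at 1.35), p53 (0.17), T and NK cell (0.15, with Prf1 at 1.82), mesenchymal (0.13, with Mmp3 at 1.46) and cell cycle (0.12, with Mad2l1 at 0.73) lists lay above the central 95% of random lists. The T and NK cell median was -0.33 when probes had to be detected at p below 0.01 on all 4 arrays. Prf1 was the only T and NK cell member higher by at least 1 in either pair. On the 9 arrays it did not follow its list. Prf1 was at 12.93 in TK/IgG replicate 1 and 10.84 in TK/IgG replicate 3, where the list means were 6.47 and 7.38. Endothelial (-0.10), pericyte (-0.05) and fibroblast (0.05) lists lay inside. Other large ratios were those of Erich5 (3.16) and Hsd3b2 (2.82). Among the largest on the lower side, for genes brighter than the median, were Eef1akmt1 (-1.69), Zfp763 (-1.67) and the granzyme genes Gzmd (-1.39), Gzmg (-1.34) and Gzme (-1.05). Among the genes fixed in advance, Angpt2 was at -0.34, Pecam1 at -0.54, Cdh5 at -0.16, Tek at 0.03 and Cspg4 at 0.07. Angpt1 and Rgs5 were at least 1.02-fold and 1.13-fold higher.

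In the late pair, 103 genes had a log2 ratio of at least 1 in size, 38 higher and 65 lower. With the authors' processed values there were 352, 168 higher and 184 lower, so that the share higher went from 36.9% to 47.7%. The fibroblast list had a median of -0.64, below all random lists, with 13 of 32 members lower by at least 1. Col1a1 was at -3.19, Col6a2 at -2.24 and Mfap5 at -2.22, and the stromal genes Dkk3, Lrrc15, Serpinf1, Loxl1 and Olfml3 at -2.34, -2.20, -2.09, -2.01 and -1.98. Endothelial genes had a median of -0.45, with 23 of 26 members lower, among them Esam (-1.07), Sox18 (-1.03) and Egfl7 (-0.94). Cdh5, not above background in the ablated tumour, was at least 1.65-fold higher in the control. Pericyte genes had a median of -0.29, with 14 of 18 lower, among them Acta2 (-1.24) and Mcam (-0.53). Skeletal muscle genes were lower, at -0.59, and at -0.21 under the stricter detection filter.

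Mast cell genes had a median of 0.97, and the tryptase gene Tpsab1 had the highest ratio among genes brighter than the median (3.15). Neutrophil genes had 0.52, with S100a9 at 1.97 and the histamine-forming enzyme gene Hdc at 1.87. The chitinase-like gene Chil3, also on the neutrophil list, went the other way at -2.19, the 1 member lower by at least 1. Interferon genes had 0.40, with 26 of 28 members higher and Ifit3 at 1.12. Chemokine genes had 0.40, with Cxcl1 at 2.44 and Ccl4 at 1.57. Epithelial (0.31, with Krt14 at 0.98), milk (0.33, with Csn3 at 0.46), T and NK cell (0.16, with Prf1 at 1.39) and hypoxia (0.13, with Car9 at 0.74) lists lay above the central 95% of random lists. Macrophage (-0.22, with C1qb at -0.81) and MHC class II (-0.28, with Cd74 at -0.75) lists lay below. Angpt2 was at 0.10, Vegfa at 0.33 and Pecam1 at -0.37. Tek and Rgs5 were at least 1.28-fold and 1.02-fold higher in the control, and Angpt1 and Cspg4 were not above background in either tumour. Across genes, the early and late ratios had a correlation of 0.0560 (rho 0.1003, 9714 genes). The late ratio and the TK/IgG minus WT/IgG difference had a correlation of 0.316 (rho 0.164) and the early ratio 0.0544 (rho 0.0795; 8889 genes), with genes not independent replicates.

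**Figure D3:**
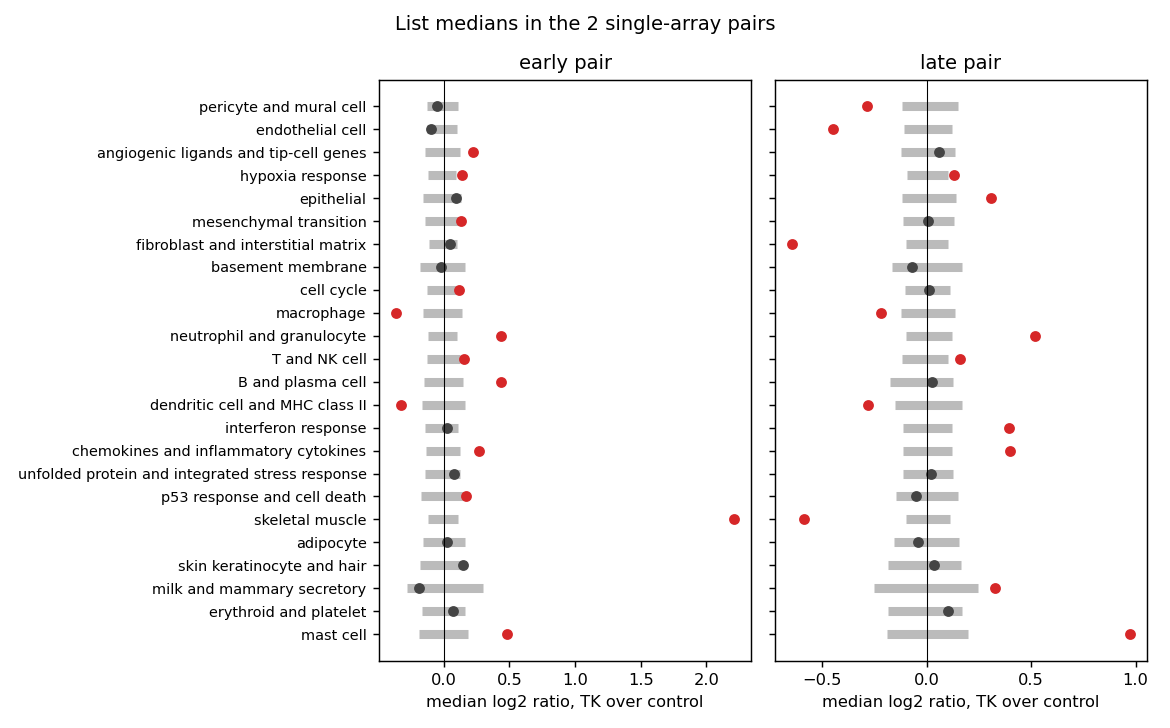
Median log2 ratio, ablated over control, of 24 gene lists in the early and late pairs (points), with the central 95% of 10000 random lists matched on signal as grey bars. Red points lie outside the bars; skeletal muscle was at 2.21 in the early and -0.59 in the late pair, and the fibroblast list at 0.05 and -0.64.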

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

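The technical and biological tests in this part were chosen after the results were seen, except the counts over other splits of the arrays. Those of array quality and of host cells were replaced after earlier versions, with other outcomes, had been seen. Among lists outside the central 95% of random lists in both pairs and named genes of at least 1 log2 in both, 8 results went in opposite directions early and late, each with 1 array on each side, and the difference was not tested. The skeletal muscle list had a median log2 ratio of 2.21 early and -0.588 late. Within it Acta1 was at 6.23 and -2.01, Myl1 at 5.41 and -1.48, Atp2a1 at 5.25 and -1.69, and Tnnc2 at 4.83 and -1.71. Fhl1, a gene of striated muscle, was at 2.76 and -1.54, the granzyme gene Gzmg at -1.34 and 1.10, and the cross-linking enzyme gene Lox at 1.35 and -1.11. On the 9 arrays the skeletal muscle list mean ran from 5.56 to 8.19 within TK/IgG. It ran from 5.71 to 9.10 within TK/anti-Ang2 and from 5.76 to 8.42 within WT/IgG. Differences of this order thus occurred between samples of 1 group, and whether ablation altered muscle genes was not tested.

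The higher fibroblast and interstitial matrix list in TK/anti-Ang2 than in TK/IgG tumours (median 0.48) rested on TK/anti-Ang2 replicate 2. Without that array the median was -0.0156. Its list means for adipocyte, skin keratinocyte and hair, and mast cell genes were 1.34, 2.54 and 2.24 above the next array. Fat, skin and other host tissue in that piece may thus have added the fibroblast genes. Low array quality cannot be told apart from this by the measures at hand. Of 4 measures, the share of probes detected was inside the range of the others (42.5%, against 40.6 to 43.2%), and 3 were outside: processed values below zero (20.5%, against 0.380 to 13.7%), the median processed value (12.6, against 14.4 to 19.4) and the median correlation with other arrays (0.966, against 0.982 to 0.989). That correlation is of unnormalised log2 signals over all probes, while the 0.931 given earlier is of normalised values of the genes tested. RNA of other tissue would also lower either correlation, so neither separates host tissue from low quality.

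The lower endothelial list in TK/anti-Ang2 than in TK/IgG tumours (median -0.49) did not come from that array, since the median was -0.579 without it. A high endothelial content of the TK/IgG arrays is argued against by -0.455 relative to WT/IgG, although that value uses the same TK/anti-Ang2 arrays. Arrays of TK/anti-Ang2 and WT/IgG also overlapped in this list mean (exact permutation p = 0.2). Set against the mean of 7 other host cell lists, the endothelial list mean differed by -0.636 in TK/anti-Ang2 minus TK/IgG (95% interval -1.16 to -0.111 over arrays). The mean of those lists itself differed by 0.171. Without TK/anti-Ang2 replicate 2 the value was -0.548 (-1.23 to 0.139) and that of the other lists 0.0305, from -0.256 for macrophage to 0.206 for dendritic cell and MHC class II genes. The other lists together were not lower, but that interval reaches past 0, so a lower share of all host cells cannot be told apart from a loss of endothelium.

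5 genes outside the neutrophil list (Erich5, Cxcl1, Gm7609, Hsd3b2 and Zxda) had log2 ratios of at least 1.5 in both pairs, ablated over control. Their mean on the 9 arrays had r = 0.0561 with the percent of probes detected (exact permutation p = 0.883, rho 0.183, p = 0.644, r = -0.262 without the 2 farthest arrays). That argues against array brightness, so measured, as a source of their spread. Other array measures were not tested. TK/IgG replicate 1 and TK/anti-Ang2 replicates 1 and 2, highest in these genes, had the most processed values below zero. These were 11.8, 13.7 and 20.5%, against 0.380 to 4.09% on the other arrays, so a technical source stays open. Hypoxia may be involved and cannot be told apart from other differences: the mean of these genes and the hypoxia list had r = 0.791 (exact permutation p = 0.0127, adjusted over 2 relations 0.0255, rho 0.683, p = 0.0503), past the 0.7 asked for at first. That verdict was made stricter after the value was seen, because 3 arrays (12.03 to 12.46) lay apart from the other 6 (9.96 to 11.02), r within the 6 was -0.359, and r was 0.578 without the 2 farthest arrays, so the relation rests on those arrays. Host genotype cannot be told apart either, with 4 of 6 TK arrays above the highest WT/IgG array.

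The 6 arrays of a comparison split into 3 and 3 in 10 ways, the real split included, too few for a share under 0.05. Genes at an unadjusted p below 0.05 numbered 325 for TK/IgG against WT/IgG (highest other split 618), 369 for TK/anti-Ang2 against TK/IgG (1581) and 817 for TK/anti-Ang2 against WT/IgG (1355). As many or more came in 8, 9 and 2 of the 10 splits, the real one included. Lists called numbered 11 (highest other 13), 6 (15) and 13 (15), and as many or more came in 2, 9 and 3 splits. The split with 1581 genes, of which 2 passed the adjusted threshold, put TK/anti-Ang2 replicates 1 and 2 with TK/IgG replicate 1. The same 3 arrays were highest in the mean of the 5 genes above. This split was singled out after the counts were seen, so a structure of the samples other than the groups was not tested. For TK/IgG against WT/IgG, the split of TK/IgG replicates 1 and 2 with WT/IgG replicate 1 called 1 gene.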

How the results depend on the processing

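All alternatives here were chosen before the data were examined, except the pooled fit given under the other observations, the orders of groups for fry and cyclic loess with normexp for the pairs. The count of genes called stayed at 0 in TK/IgG minus WT/IgG and TK/anti-Ang2 minus TK/IgG under every alternative run. In TK/anti-Ang2 minus WT/IgG it was 1 in some settings, namely Slc24a3, whose limma adjusted p over all alternatives ran from 0.0278 to 0.573. It passed with cyclic loess (limma adjusted p = 0.0431), with detection p below 0.01 on all 9 arrays (0.0278, with fewer genes tested) and with array weights (0.0404). The cause was not tested for the first and last.

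With an estimated correlation 0 lists were called in each comparison. The calls of the fibroblast (-0.54), endothelial (-0.49) and chemokine (0.91) lists ended. Their medians could not change, since this setting uses the same fit. That test allows for correlated members, but this alone does not account for the higher p of every list. The basement membrane list in TK/anti-Ang2 minus WT/IgG had an estimated correlation of 0.00328, below the preset 0.01. Its unadjusted camera p still rose, from 0.0109 preset to 0.0376 estimated, which a lower correlation cannot explain. Its call ended too (camera adjusted p = 0.0209 preset, 0.313 estimated). What ended the calls of the other lists was not tested. When each array was left out, lists called ranged from 7 to 12 for TK/IgG minus WT/IgG and from 6 to 13 for TK/anti-Ang2 minus TK/IgG, with the 7 and the 13 both seen without TK/IgG replicate 3. For these the cause was not tested.

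When each array was left out, Pecam1 in TK/IgG minus WT/IgG ranged from -0.0738 (without WT/IgG replicate 2) to 0.55. Ranges in TK/anti-Ang2 minus WT/IgG were -0.15 to 2.90 for Krt15, -0.40 to 2.90 for Lce1c, -0.14 to 2.53 for Krt10 and -0.27 to 2.38 for the skin list, each lowest without TK/anti-Ang2 replicate 2. The fibroblast list in TK/anti-Ang2 minus TK/IgG ranged from -0.0156, without that array, to 0.78. T and NK cell and interferon lists in TK/IgG minus WT/IgG ranged from -0.21 to 0.50 and from -0.10 to 0.39, lowest without TK/IgG replicate 3. In these fits fewer samples carry the group mean.

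In the early pair 106 genes of at least 1 log2 became 201 with the authors' processed values and 60 with detection p below 0.01 on all 4 arrays, where fewer genes enter; the T and NK cell median was then -0.33. In the late pair 103 became 352 with the authors' processed values. The cause was not tested. Dim signal limits these ratios, since a probe not above background gives only a bound.

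The replicate numbers did not pair the samples throughout: same-numbered arrays deviated together with r from -0.162 to 0.391, above 0.1 in 3 of 9 pairs, and 4 of 9 arrays correlated best with their own number. The highest r of any pair of arrays, 0.391 and 0.348, were between same-numbered ones. Replicate 3 of each group was also highest for skeletal muscle genes. Its list means were 8.19 in TK/IgG, 9.10 in TK/anti-Ang2 and 8.42 in WT/IgG, against 5.56 to 7.20 on the other arrays. A factor shared by same-numbered arrays is thus not excluded. With the replicate number as a block, 0 genes were called in each comparison and 13, 8 and 13 lists, holding all 11, 6 and 13 called without the block. Slide as a block was not run, since the tables name no slides.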

Other observations

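The pooled comparison in this part was chosen after the results were seen. With the 6 TK arrays as 1 group against the 3 WT/IgG arrays, limma called 0 genes, with 583 at an unadjusted p below 0.05, and arrays did not overlap for 2.82% of genes, where chance gives 2.38%. Slc24a3, a sodium/calcium-potassium exchanger, was at 7.54 ± 0.23 (SD, n = 6) against 6.17 ± 0.19 (n = 3), with a limma adjusted p of 0.0715. Gpnmb, a glycoprotein of lipid-laden macrophages, was higher by 1.48 (SE 0.20, limma adjusted p = 0.137) and Msx1 lower, at -1.01 (SE 0.16, limma adjusted p = 0.3505). Pdgfrb differed by -1.09 (SE 0.21, limma adjusted p = 0.549), with an exact permutation p of 0.0119, the smallest that 84 splits allow, and was lower in all 6 TK arrays than in any WT/IgG array. C1qtnf3 and Atp2c2, named after their values were seen, were at -1.39 and -0.69 and likewise did not overlap.

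In both pairs the same 4 genes of the neutrophil and granulocyte list, Cstdc4, Hdc, Retnlg and S100a9, had log2 ratios of at least 1.5 in the ablated tumour. Their early and late ratios were 2.04 and 1.61, 1.67 and 1.87, 2.13 and 1.54, and 1.85 and 1.97. No gene was lower by as much in both. The mast cell list also lay above the random lists in both pairs (0.48 and 0.97), and which cells carried Hdc was not tested.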
